A study of Mus musculus with 6 samples.

How the data were processed

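RNA of Ba/F3 cells with doxycycline-inducible PAX5-KIDINS220 was measured on Affymetrix Mouse Genome 430 2.0 arrays, 3 without and 3 with 500 ng/mL doxycycline for 24 h. Groups came from the source names in the labels. Replicate numbers were given in the order of the samples and were not used as pairs; the 2 arrays numbered 1 share an array code, and the others do not. The values deposited by the authors are linear signal intensities per probe set, made with Affymetrix Expression Console per the submitters' processing notes; its algorithm and version are not given in the sources used here. From the values, each array had been scaled to the same mean after trimming 2% at each end (500), and no further normalization between arrays was seen. Such scaling sets the average of every array equal, so a change in total mRNA would not show. Precision is limited by the number of arrays, and no detection calls were used here.

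Gene names came from the platform annotation, updated through Entrez identifiers, which changed 0 symbols. Of 45101 probe sets, 64 were controls. Of the 45037 others, 34945 had 1 symbol, 932 had several and 9160 were not listed in the annotation used here and were left unnamed. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays. Signals were transformed to log2(signal + 16), so fold changes are on that scale and understate changes of dim genes. No filter on dim genes was applied.

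Before the data were examined, the following were fixed: the comparison, the fit, the 25 gene lists, the alternatives and the rule for named genes. The fit was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) with doxycycline as the only term, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Array codes in the sample titles were grouped here by how they start, into a set of 2 arrays with a shared code and a set of 4 with separate codes. The labels do not say that these codes mark a batch, so a fixed block for the set, and a fit of the 4-array set alone, were planned as alternatives. Since 6092 genes differed between the sets, the blocked values are given beside those without a block. In the 4-array set there are 2 arrays per group, and in the 2-array set 1 per group, which gives ratios with no test.

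Named genes were those past the threshold without the block, up to 12 in each direction. As none passed, the 12 with the smallest p in each direction were named, without clone, Gm, expressed-sequence and LOC symbols (3 skipped), with Pax5, Kidins220 and up to 4 members per list by the smallest p. The 36 genes called with the block, Gzmb and some further genes lie outside this rule and were chosen after their values were seen. Of the 25 lists, 24 were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry (1 direction, and either direction); the other held only Pax5 and Kidins220. Members were also tested adjusted over the list alone. One list member is not reported here. A camera test of the interaction between doxycycline and array set compared the response of each list in the 2 sets; it assumes that the lone arrays of the 2-array set vary like those of the 4-array set.

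The alternatives were quantile normalization, median centring, no trend, a robust prior, leaving out genes under the 40th percentile of mean signal, the mean of all probe sets, leaving out probe sets ending in _s_at, _x_at or _a_at, array weights, pseudocounts of 1 and 64, every probe set by itself, an adjusted p under 0.10 and leaving out each array in turn. The same alternatives were run with the block after the data were seen. A direction was scored as reversed where at least 1 of the settings compared was past the threshold. RNA quality was compared with two-sided exact permutation tests.

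The fits were tested on simulated data for the comparison with against without doxycycline. These held 18193 genes with the array-set differences and residual spread of the blocked fit. The 200 changed genes were drawn from those above the 40th percentile of mean signal. The recovered shares therefore do not cover dim genes. Without the block, 0%, 4.48% and 47.0% of genes changed 1.5-, 2- and 4-fold were recovered, and with it 32.8%, 59.7% and 92.4%. Without the block 34 genes were called, 0 of them falsely, and with it 129, 6 of them falsely. The simulated noise was drawn for each gene independently. In the real blocked fit, the correlation that camera estimated within a list ran from -0.063 (neurotrophin and KIDINS220) to 0.74 (S phase). The false calls in the simulation therefore do not give the rate of the real fit.

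One of the tests of explanations was computed in a second form after its result was known. The ratio of the residual SD without and with the block was 1.83 at the median of the genes above the dim limit. Recomputed for the 36 called genes alone it was 8.00, but those genes were picked by passing with the block only, which raises the ratio, so the first value is the one used. The test of eosinophil-associated genes in the 2-array set was also narrowed after its first result, to the 3 genes that passed in the 4-array set alone; the median did not change at the digits printed. Those 3 genes were first picked from the blocked calls, so this test decides nothing.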

Results

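Gene expression was measured on 6 Affymetrix arrays in Ba/F3 cells, a mouse haematopoietic line that depends on interleukin-3 and was grown here with WEHI-3 supernatant. The cells carried PAX5-KIDINS220 under a Tet-on promoter, so that doxycycline switches the fusion on. PAX5 is the transcription factor that commits cells to the B lineage, and KIDINS220 is a membrane scaffold protein of neurotrophin and antigen receptor signalling. RNA was taken after 24 h for 3 samples without and 3 with 500 ng/mL doxycycline, and the stated question was which pathways the fusion affects. The labels do not say whether the 3 samples of a group were grown separately, so p-values describe the spread between these arrays, which may be technical. By the start of their array codes, the arrays were grouped here into a 2-array set (1 without, 1 with doxycycline) and a 4-array set (2 of each). The labels do not name these sets. In the 4-array set each array had its own code, and those of the treated arrays came before those of the untreated. A difference that follows the code order there cannot be told apart from treatment. Each array had the same trimmed mean signal of 500, and the median signal of a probe set was between 56.3 and 65.6.

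The Pax5 probe set 1421765_at had signals of 15.6, 3.76 and 20.3 without doxycycline and 119, 94.5 and 94.2 with it. The means were 13.2 ± 8.54 and 103 ± 14.1 (SD, n = 3 arrays each), a log2 difference of 2.06 (SE 0.33), with ratios of 2.09 in the 2-array set and 2.04 in the 4-array set. By p-value it ranked 4 of 45037 probe sets, but its limma adjusted p was 1.0 without and 0.12 with a block for the array set, so it did not pass the test. The brighter Pax5 probe set 1454401_at differed by 0.21 (SE 0.52, no block). The 4 Kidins220 probe sets differed by -0.08 to 0.26 on the log2 scale, and none passed. Which part of each transcript these probe sets read, and whether they detect the transduced fusion, is not known here, so the values do not check the labels.

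With a block for the array set, 27 genes were higher and 9 lower with doxycycline (limma, Benjamini-Hochberg adjusted p under 0.05, 18193 genes tested), 2 and 1 of them by at least 2-fold. Pla2g4c, a cytosolic phospholipase A2, rose 4.29-fold (95% interval 2.96 to 6.21, limma adjusted p 0.017), from 83.3 ± 11.3 to 420 ± 126 (SD, n = 3 each). St8sia4, a polysialyltransferase, rose 2.03-fold (1.80 to 2.29, limma adjusted p 0.0058), from 4175 ± 175 to 8564 ± 1439. Nebl, which encodes the actin-binding protein nebulette, fell to 0.366 of its level (0.263 to 0.509, limma adjusted p 0.040). Prkar2b, a regulatory subunit of protein kinase A, fell to 0.526 (0.459 to 0.601, limma adjusted p 0.0079). The 36 genes were chosen after their values were seen. Without the block, which is the fit set before the data were examined, limma called 0 genes higher and 0 lower. At an unadjusted limma p under 0.05 that fit held 464 genes. The fit with the block held 2012 such genes, and that of the 4-array set alone 2360. Chance gives 910 where the arrays of a group vary at random. Without the block each group mixes arrays of both sets, so 464 against 910 does not show a lack of response.

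With the block, Vsir (VISTA, an inhibitory receptor) rose 1.93-fold, Gpr174 (a receptor for lysophosphatidylserine) 1.92-fold, Siglecf (an inhibitory lectin of eosinophils) 1.92-fold and Pirb (an inhibitory receptor for MHC class I) 1.78-fold, with limma adjusted p of 0.026, 0.031, 0.017 and 0.0079. Cd55, a complement regulator that stood in the list of genes activated by PAX5, rose 1.69-fold (limma adjusted p 0.0079), and the tetraspanin Cd53 1.61-fold (0.022). Gata1, the erythroid, mast cell and eosinophil transcription factor, rose 1.57-fold (1.39 to 1.77, limma adjusted p 0.020). Its signals were 1702, 2642 and 2517 without and 3059, 3609 and 3983 with doxycycline. Smaller rises were those of Prg2 (eosinophil major basic protein, 1.33-fold), Ncf1 (a subunit of the NADPH oxidase, 1.35-fold) and Tyrobp (the adaptor DAP12, 1.32-fold). Metabolic genes among the 27 were Cyp11a1 (side-chain cleavage of cholesterol, 1.66-fold), Acss2 (acetyl-CoA synthesis, 1.39-fold) and Idh1 (isocitrate dehydrogenase, 1.44-fold). The others that rose were Mrtfa, St3gal2, Cklf, Vopp1, Tfr2, Klf6, Tle6, Slc35e3, Vwa5a, Cela1, Furin and Gda, by factors of 1.33 to 1.62. Besides Nebl and Prkar2b, the transporter gene Slco4a1 fell to 0.557, Mamdc2 to 0.588, Cpne2 to 0.617, Nmral1 to 0.623, the chemokine receptor gene Ccr1 to 0.67, Tmem51 to 0.69 and Igf1r, the IGF-1 receptor, to 0.716. Without probe sets ending in _s_at, _x_at or _a_at, Nmral1 turned to 0.074 and Cklf to -0.12 on the log2 scale.

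Of the 75 genes that passed in the 4-array set by itself, 60 had the same sign in the 2-array set. All 36 genes had the same sign in both sets, but they were picked by a fit that averages the sets. Of the 36, 24 also passed in the 4-array set by itself, and in 12 the 3 arrays of one group lay wholly apart from the 3 of the other. Over all genes tested 1250 were so separated, 6.87%. Chance gives 10% only for interchangeable arrays. Each group here held arrays of both sets, so the 10% is no baseline for that share. The 4-array set alone gave 55 higher and 20 lower genes, 10 and 2 of them by at least 2-fold. In the 2-array set, with 1 array per group, the 27 higher genes called with the block had a median log2 ratio of 0.46 and the 9 lower ones -0.78, against 0.68 and -0.65 in the 4-array set. The blocked calls depended on the mean-variance trend and on single arrays. There were 0 calls in all without the trend, without replicate 3 of the untreated group or without replicate 2 of the doxycycline group. A robust prior left 37 calls, 35 of them among the 36. Why the calls were lost without the trend was not tested. There were 3 calls without replicate 2 of the untreated group and 5 without replicate 3 of the doxycycline group. Without the untreated or the treated array of the 2-array set there were 66 or 68. In those fits the block absorbs the array left over, so the log2 differences are those of the 4-array set alone.

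**Figure D1:**
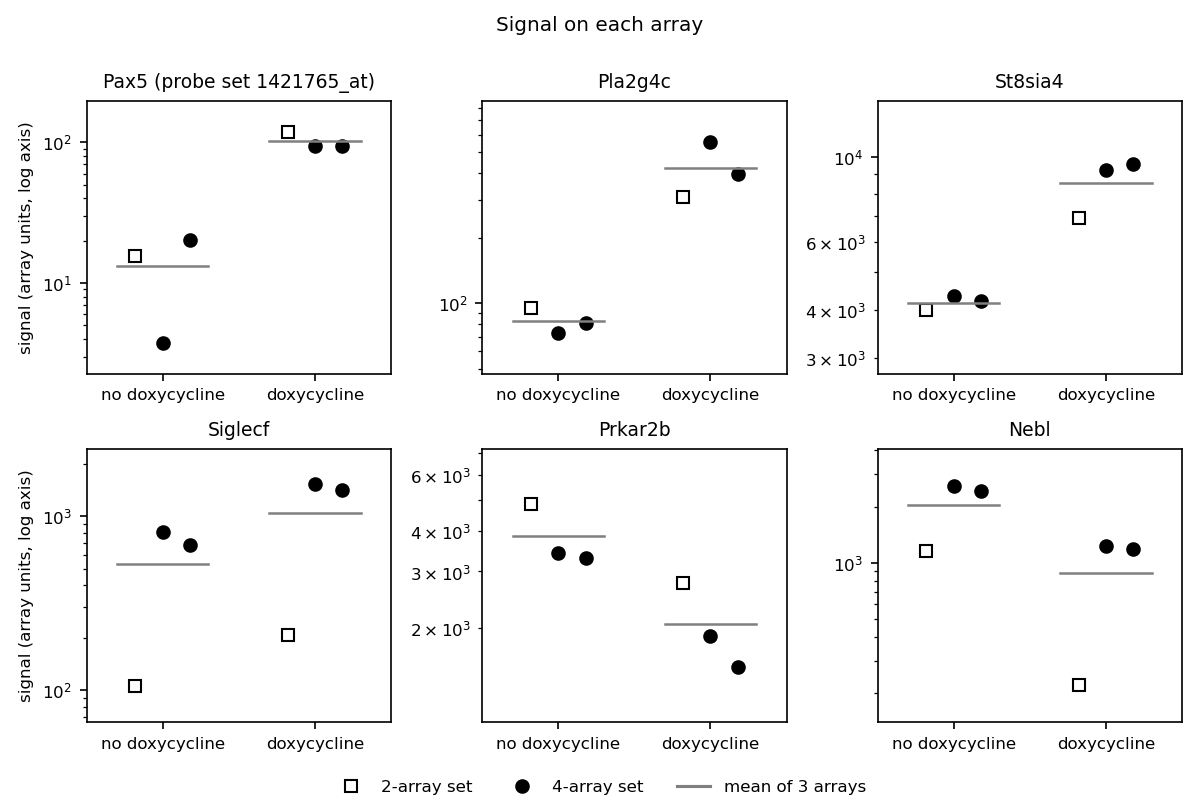
Signal on each of the 6 arrays (array units, log axis) for Pax5 probe set 1421765_at and 5 genes, without and with doxycycline; squares are the 2-array set, circles the 4-array set, and grey lines the mean of 3 arrays. The Pax5 probe set was between 3.76 and 20.3 without and between 94.2 and 119 with doxycycline, while the Siglecf signals without doxycycline ranged from 105 in the 2-array set to 810 in the 4-array set.

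The 24 genes named for the smallest p in the fit without a block, 12 in each direction, did not pass there (limma adjusted p of 1.0). Of the 12 higher ones, 4 passed with the block (Pla2g4c, St8sia4, Cklf and Gpr174), and of the 12 lower ones 1 did (Slco4a1). The other higher ones were dim: Krtap3-1 (log2 difference 1.91), Alppl2 (1.69), Pramel18 (1.11), Arhgef25 (1.57), Ydjc (1.11), Pou3f4 (1.23), the p53 target Plk2 (1.02) and Ccr3, the eotaxin receptor gene (2.14). Ccr3 had signals of 4.11, 6.23 and 4.97 without and 37.1, 137 and 81.7 with doxycycline (blocked limma adjusted p 0.075). The lower ones were Art5 (-1.56), the aryl hydrocarbon receptor target Cyp1a1 (-1.26), Adgrb3 (-1.05), Foxc1 (-1.07), Vmn1r40 (-1.10), Pde3a (-1.13), Mmel1 (-1.39), Klhl35 (-0.92) and Tekt5 (-1.15), with Tesc at 0.499 and the basophil protease gene Mcpt8 at 0.498 of their levels. The median of the genes' mean signals was 41.2 for the higher and 19.8 for the lower ones.

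By camera at its preset correlation, genes of cell growth and division were lower with doxycycline as groups. The fall was in the 4-array set and not in the 2-array set, and no call held with an estimated correlation. All 24 measured genes of the list for MYC and ribosome biogenesis had negative log2 differences (median -0.17), as did all 21 S-phase genes (-0.21) and all 20 G2/M genes (-0.21). Their camera adjusted p were 0.031, 0.048 and 0.0063 without a block and 4.1e-09, 8.5e-10 and 1.4e-10 with it. Without the block, the MYC and S-phase calls were lost with median centring and without probe sets ending in _s_at, _x_at or _a_at, and the S-phase call also with the mean of all probe sets; the G2/M call held in these 3 settings. No list passed with an estimated correlation, where the adjusted p was 0.91 without and 0.62 with the block for each of the 3. None passed by fry for 1 direction either (blocked adjusted p 0.41). By fry for either direction the 3 did not pass with the block (adjusted p 0.16, 0.16 and 0.11). In the 4-array set alone that test passed for them (0.014, 0.030 and 0.026). In single genes, Mki67 was at -0.48 (SE 0.08, blocked limma adjusted p 0.073), Gins1, a replication helicase subunit, at -0.54 (0.14) and Cad, of pyrimidine synthesis, at -0.44 (0.085). No member of the 3 lists passed over all genes without or with the block. In the 4-array set alone 1 of each fell: Fbl at -0.59, Rrm2 at -0.49 and Mki67 at -0.60 (limma adjusted p 0.022, 0.043 and 0.028). Adjusted over the list alone, 2 of the MYC list, 4 of the S-phase list and 4 of the G2/M list fell with the block, and 18, 14 and 18 in the 4-array set. The fall was not seen in both array sets: the medians were -0.28, -0.32 and -0.31 in the 4-array set and 0.05, -0.01 and 0.03 in the 2-array set. The 3 lists were also lower in the 4-array than in the 2-array set whatever the treatment, with medians of -0.89, -1.09 and -0.85.

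Genes of cholesterol synthesis were higher as a group, with positive differences in 15 of 17 measured (median 0.19, camera adjusted p 0.0063 without and 2.9e-04 with the block). With an estimated correlation it did not pass (adjusted p = 0.91 without and 0.62 with the block). Without the block the call was also lost with the mean of all probe sets and without probe sets ending in _s_at, _x_at or _a_at, while with the block it held in both. Examples were Fdps at 0.30 (SE 0.07), Sqle at 0.26 (0.06) and Hsd17b7 at 0.24 (0.09). Adjusted over the list alone, 2 rose with the block and 11 in the 4-array set, and over all genes none in either. The group's median was 0.28 in the 4-array set and -0.10 in the 2-array set. The list of endoplasmic reticulum chaperones was higher with the block (median 0.08, 14 of 19 positive, camera adjusted p 0.0059) and in the 4-array set alone (0.021). It did not pass without the block (adjusted p 0.20), nor with an estimated correlation (adjusted p = 0.62 with the block and 0.61 in the 4-array set). By fry with the block the adjusted p was 0.36 for 1 direction and 0.0026 for either direction. Among its members were Dnajb11 at 0.26 (SE 0.06) and Edem1 at 0.29 (0.06). Adjusted over the list alone, 2 of its members rose. The chaperone medians were 0.15 in the 2-array set and 0.08 in the 4-array set. The ATF4 amino acid response list was lower (median -0.06, 17 of 26 negative, camera adjusted p 0.0059) with the block. It did not pass without the block (adjusted p 0.61), nor with the block and an estimated correlation (adjusted p = 0.62). Among its members were Shmt2, of serine and glycine metabolism, at -0.32 (SE 0.06) and Ddit3 at 0.25 (0.10). Adjusted over the list alone, 2 of its members fell. The ATF4 list medians were -0.10 in the 2-array set and -0.08 in the 4-array set.

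**Figure D2:**
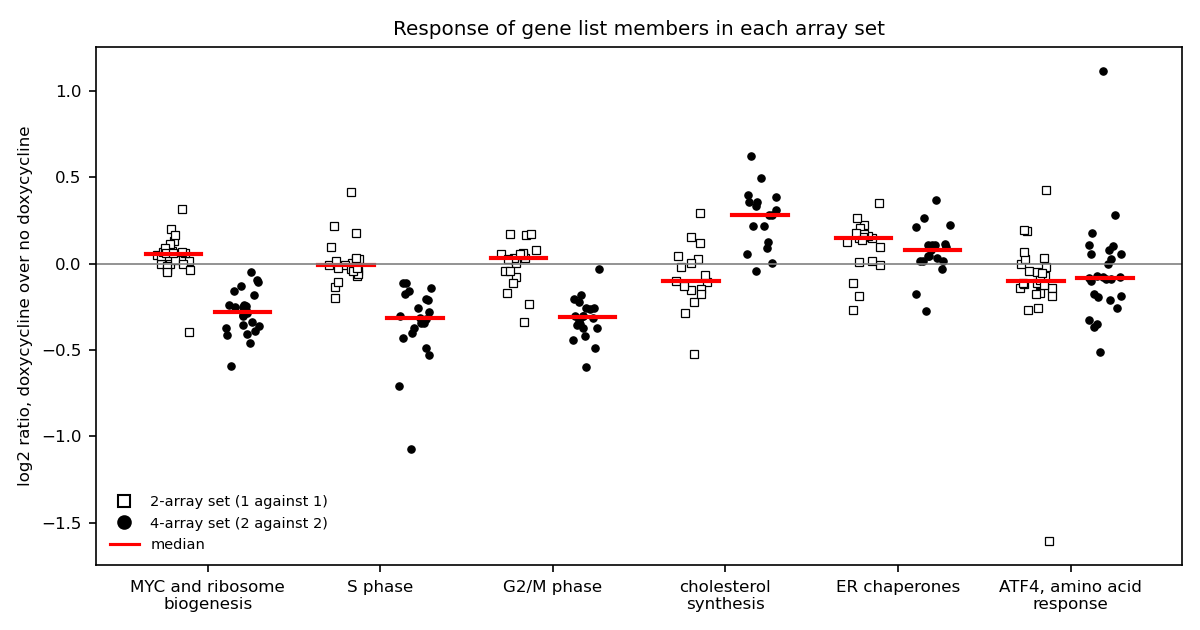
Log2 ratio of doxycycline over no doxycycline for each measured member of 6 gene lists, in the 2-array set (squares, 1 array against 1) and the 4-array set (circles, 2 against 2); red lines are medians. The MYC, S-phase and G2/M medians are -0.28, -0.32 and -0.31 in the 4-array set and near 0 in the 2-array set.

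Neither list of PAX5 targets passed the directional tests, camera and fry, without or with the block. With the block, fry for changes in either direction passed for the PAX5-activated list (adjusted p 0.0026), the PAX5-repressed list (0.012) and the early B-lineage list (0.048). That test does not compare a list with other genes, and without the block it passed for no list (lowest adjusted p 0.23). Of 20 measured PAX5-activated genes 7 were positive and 13 negative (median -0.11, blocked camera adjusted p 0.61). Over all genes Cd55 alone passed, and adjusted over the list alone 1 rose and 1 fell. Cd72, a B cell coreceptor, was at -0.68 (SE 0.18, blocked limma adjusted p 0.21), and Blnk, the B cell linker, at -0.94 (SE 0.37). Blnk was dim, with signals of 2.40 to 45.5, and was at -1.42 in the 4-array set and 0.04 in the 2-array set. Of 16 PAX5-repressed genes 11 were positive (median 0.09, camera adjusted p 0.96), with Cd28 at 0.68 (SE 0.46) and Prdm1 at -0.45 (SE 0.34). None of these 16 passed over all genes, and 1 fell with adjustment over the list alone. The early B-lineage list was positive in 15 of 21 (median 0.17, camera adjusted p 0.12), with Btk at 0.18 (SE 0.06), Syk at 0.26 (0.09), Ms4a1 (CD20) at 0.49 (0.31) and Il7r at -0.53 (0.31). None of the 21 passed over all genes with the block, while 1 rose and 1 fell with adjustment over the list alone. In the 4-array set by itself Ighm rose (1.45, limma adjusted p 0.0057), while its ratio in the 2-array set was 0.08.

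Signalling and survival lists did not pass the directional tests with the block. For changes in either direction, fry with the block passed for the ERK list (adjusted p 0.0022), the p53 list (0.0045) and mitochondrial ribosome genes (0.0095). The interleukin-3 and STAT5 list had a camera adjusted p of 0.41, the ERK and immediate early list 0.73 and the NF-kappaB list 0.25. Within the first, Myc was at -0.36 (SE 0.07, limma adjusted p 0.11) and Il2ra at -1.12 (SE 0.24), while Pim1 was at -0.14 (SE 0.07). In the other 2 lists, Fos was at 0.45 (SE 0.16), Fosl1 at -0.69 (0.23) and Nfkbia at 0.52 (0.14). The p53 list had a camera adjusted p of 0.098, with Gadd45a at -0.38 (SE 0.07), and the BCL2 family 0.67, with Bcl2 at -0.27 (0.10) and Bcl2l2 at 0.31 (0.09). The interferon list (0.91), the neurotrophin and KIDINS220 list (0.96), glycolysis (0.34), nuclear oxidative phosphorylation genes (0.25) and mitochondrial ribosome genes (0.088) did not pass either. In the 4-array set alone the mitochondrial ribosome list was lower (median -0.09, 22 of 25 negative, camera adjusted p 0.0064), but not with an estimated correlation (0.65). Among the members of these 5 lists, Ifit2 was at -0.35 (SE 0.08), Ntrk3 at 0.21 (0.32), Slc2a1 at 0.19 (0.09), Ndufs1 at -0.17 (0.07) and Mrpl16 at 0.42 (0.07, limma adjusted p 0.065). No member of these 10 lists passed over all genes with the block, and in the 4-array set 1 did (Nfkbia, 0.78, limma adjusted p 0.021). In the 2-array set the log2 ratio of Nfkbia was 0.005. Adjusted over the list alone, with the block, 2 interleukin-3 and STAT5 genes fell, 1 ERK gene rose and 2 fell, 1 p53 and 1 interferon gene fell, 1 mitochondrial ribosome gene rose, and 0 changed in the remaining lists.

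Markers of other blood lineages did not move in 1 direction as groups with the block. For changes in either direction, fry with the block passed for the erythroid and megakaryocyte list (adjusted p 0.0026), mast cells and basophils (0.026) and T cells (0.035). The camera adjusted p was 0.48 for T cells, 0.91 for granulocytes and monocytes, 0.67 for mast cells and basophils, 0.13 for the erythroid and megakaryocyte list and 0.34 for plasma cells. Over all genes, Gata1 of the erythroid list alone passed with the block. In the 4-array set Ms4a2 of the mast cell list passed as well (0.76, limma adjusted p 0.029), while its ratio in the 2-array set was -0.01. Adjusted over the list alone, 3 mast cell and basophil genes rose and 2 fell, 1 erythroid gene rose and 1 T cell gene fell. Of the mast cell and basophil genes, Il4 was at 1.05 (SE 0.34) and Cpa3 at 1.05 (0.34), with mean signals of 35.9 and 12.9 without and 101 and 42.9 with doxycycline. Lat, a T cell adaptor, was at -0.62 (SE 0.15), Mrc1 of the granulocyte and monocyte list at -0.87 (0.34) and Irf4 of the plasma cell list at -0.71 (0.33).

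The arrays differed more between the 2 sets than between treatments. The first principal component held 68.8% of the variance and separated the sets. The second held 9.60% and ran from -19.4 to -4.46 on the untreated arrays and from 7.58 to 20.1 on the treated ones. With doxycycline in the model, 6092 genes differed between the sets at a limma adjusted p under 0.05, 228 of them by at least 4-fold. Prg2 had a mean signal of 178 in the 2-array set and 17938 in the 4-array set, Cxcr4 935 and 13698, Trib3 2781 and 268 and S100a8 1502 and 141. The RNA quality measures did not follow treatment: the 3' minus 5' log2 difference of the Actb control probe sets was 0.26 ± 0.03 without and 0.27 ± 0.04 with doxycycline (SD, n = 3 each, two-sided exact permutation p = 0.90). For Gapdh the values were -0.58 ± 0.06 and -0.58 ± 0.03 (exact permutation p = 0.80, where 3 against 3 cannot go below 0.10).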

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

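The tests of the added spread, of a response in the 4-array set only and of the baseline of eosinophil-associated genes were chosen after the results they bear on had been seen, as were the interaction tests of gene lists. The others were written down first.

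Camera on the interaction of doxycycline with the array set passed for 6 lists at the preset correlation. With an estimated correlation none of the 6 passed (camera adjusted p 0.70 for 5 of them and 0.87 for the mitochondrial ribosome list). With 1 array per group in the 2-array set (2 residual degrees of freedom in all), the interaction test does not separate a different response from a difference between single samples. At the preset correlation the camera adjusted p was 5.09e-13 for MYC and ribosome biogenesis, 1.3e-09 for S phase, 3.12e-10 for G2/M and 7.54e-10 for cholesterol synthesis. It was 0.00691 for mitochondrial ribosome genes (medians 0.03 in the 2-array and -0.09 in the 4-array set) and 0.021 for the interferon list (-0.09 and 0.11). For single genes the interaction passed for 0 of 18193 by limma, with 1224 at an unadjusted p under 0.05.

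Taken as 1 group of 65 genes, the MYC, S-phase and G2/M genes had a median log2 difference of -0.20 with the block. The median stayed at -0.21 under quantile normalization and -0.176 under median centring, which argues against the choice among these scalings as the source. Each of them sets the arrays to a common level, so the test cannot decide whether a change in total mRNA was hidden. Without the block, 2 of the 3 lists (MYC and S phase) did not pass under median centring. The steady median therefore bears on the size of the fall and not on the unblocked calls. The median was -0.30 in the 4-array set, with 65 of 65 negative, and 0.0212 in the 2-array set, with 26 of 65 negative, so the fall may belong to the 4-array set alone (interaction camera p 6.9e-25, and 0.088 with an estimated correlation). What sets the arrays of the 2 sets apart is not stated, and with 1 array per group in the 2-array set a difference between single samples stays open. Doxycycline itself cannot be told apart from the fusion, since 0 arrays of treated cells without the fusion were used here.

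Genes that passed with the block only form the next pattern. Each group held 1 array of the 2-array set and 2 of the 4-array set, so log2 differences were the same in both fits. Calls made only with the block therefore came through the estimate of error, as for Siglecf (SE 0.99 without and 0.10 with). Of the 36 genes, 32 differed between the sets, though they were picked by passing with the block. At the median gene above the dim limit, the residual SD was 1.83 times as large without the block. That lies between the limits of 1.5 and 2 set for the test, so it leaves open how widely a set difference widened the spread. Loss of a single array left the median size of the 36 log2 differences at 0.951 or more of its value. Those genes were picked from the fit with all 6 arrays, so the steady median is no independent check. Single genes moved (Nebl from -1.45 to -1.03 without either array of the 2-array set, which leaves the difference of the 4-array set alone). The calls fell to 0 without replicate 3 of the untreated group or replicate 2 of the doxycycline group, and the cause was not tested. Among the 6 splits that part the pair of the 2-array set, 1 gave as many genes, the real one with 36, and the highest other gave 0; 6 splits are too few for a share under 0.05. Without the block, 10 of 10 splits gave as many as the real 0, and the highest other was 0. No split can give fewer than 0, so the 10 of 10 was fixed in advance and decides nothing. Induction of the fusion is the biological explanation the design gives, and it was not separable from doxycycline.

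Siglecf, Prg2, Pirb and Gata1, which passed with the block, and Ccr3, which did not, are known from eosinophils among other cells; they were put together after their values were seen. Siglecf, Pirb and Gata1 also passed in the 4-array set by itself. Their median log2 ratio in the 2-array set was 0.88, but they were first picked from a fit that uses that set, so whether the rise belongs to the set with the higher baseline stays open. A wider eosinophil programme was tested on 9 other eosinophil genes, of which 5 were measured. As a list they did not pass (camera p 0.41, 3 of 5 positive). The 3 with a mean signal above 100 (Epx 0.54, Prg3 0.14 and Ccl6 -0.21) had a median of 0.136, between the limits set for the test, which leaves a wider programme open. Which cells carry these transcripts was not tested.

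Outside the gene test, 3 probe sets with no or several symbols passed with the block. Probe set 1417714_x_at, which is assigned to both Hba-a2 and Hba-a1, was lower (-0.88), 1424727_at was higher (0.78) and 1435640_x_at lower (-1.31).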

How the results depend on the processing

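The alternatives to the blocked fit, other than no block, were chosen after seeing the data. Without the block, counts of called genes were 0 under every alternative run except the block (27 higher and 9 lower; 2 and 1 by at least 2-fold) and the 4-array set alone (55 and 20; 10 and 2). The blocked counts became 0 and 0 (0 and 0 by at least 2-fold) without the trend (the cause was not tested), and 0 and 0 (0 and 0) without the block. They were 63 and 41 (4 and 3) without dim genes, 8 and 5 (1 and 0) with the mean of all probe sets, 41 and 20 with a pseudocount of 1, 17 and 5 (0 lower by 2-fold) with 64, 60 and 35 (4 higher by 2-fold) at an adjusted p under 0.10, and 1 higher by 2-fold without _s_at, _x_at and _a_at probe sets. Leaving out each array in turn gave 0 to 49 higher, 0 to 20 lower, 0 to 10 higher by 2-fold and 0 to 1 lower by 2-fold. The 36 genes kept their sign wherever they were measured (33 of them without _s_at, _x_at and _a_at probe sets, all in the other settings), except Cklf (-0.12) and Nmral1 (0.074), which reversed without those probe sets; the cause was not tested. The median absolute log2 difference of the 36, which were picked from the blocked fit of all arrays, stayed between 0.555 and 0.673.

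Of the lists, 1 was higher and 3 lower without the block (fry in this paragraph is for 1 direction). Higher lists numbered 2 with the block or in the 4-array set alone, and 0 with the mean of all probe sets, without _s_at, _x_at and _a_at probe sets, with an estimated correlation or by fry. Lower lists numbered 1 with median centring or without those probe sets, and 0 with an estimated correlation or by fry. With the block (2 higher, 4 lower), both became 0 with an estimated correlation or fry, and without the block 1 was higher. Leaving out each array gave 0 to 2 higher and 0 to 6 lower lists without the block. Without replicate 1 of the untreated group, and no block, the medians of the MYC, S-phase and mitochondrial ribosome lists reversed; that setting leaves the array sets unbalanced between the groups. Over all arrays left out in turn these medians ran from -0.47 to 0.057, -0.62 to 0.10 and -0.35 to 0.21. The ATF4 list did not pass in the 4-array set alone (adjusted p 0.055). No paired analysis was run, because the labels state no pairs beyond the code shared by the arrays numbered 1. Signal over background limits the dim genes: the 12 lower ones named by p had a median mean signal of 19.8.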

Other observations

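Some list members outside the genes called with the block had values of interest in the array sets. Il2ra, the interleukin-2 receptor alpha chain, had a mean signal of 1347 in the 2-array set and 123 in the 4-array set, and a log2 difference with doxycycline of -1.86 in the first and -0.76 in the second. Gzmb, granzyme B, was at -0.88 with the block (limma adjusted p 0.22), with -1.83 in the 2-array and -0.41 in the 4-array set. Ighm, the IgM heavy chain, had a mean signal of 12.1 in the 2-array set and 934 in the 4-array set, and differed with doxycycline by 0.99 with the block (limma adjusted p 0.21). The difference was 0.08 in the 2-array set and 1.45 in the 4-array set, where it passed (limma adjusted p 0.0057). Ceacam1, of the PAX5-repressed list, was at -0.42 with the block (limma adjusted p 0.063), with -0.46 in the 2-array and -0.40 in the 4-array set.

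The array sets differed in several lists whatever the treatment, by camera on the set term. That test was run at the preset correlation only, so whether these calls hold with an estimated correlation is not known. The mitochondrial ribosome list had a median of -0.81 in the 4-array relative to the 2-array set (adjusted p 1.1e-14) and the ATF4 list -1.09 (3.5e-10), with Trib3 at -3.30 and Nupr1 at -3.24. The early B-lineage list was higher in the 4-array set (median 0.39, adjusted p 0.040). What the array codes stand for is not given in the labels, and no explanation was tested.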
